A study of Mus musculus with 27 samples.

How the data were processed

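Ribosomal RNA-depleted total RNA was sequenced as stranded 100 bp paired reads from chromatin, nucleoplasm and cytoplasm of mESC, mNPC and mCtx, with 3 biological replicates per group. The submitters' processing notes name STAR, featureCounts and kallisto, with no versions and no roles, and the mm10 build. The deposited count table holds whole-number read counts for 37332 genes in 27 libraries, and the deposited counts are not estimated counts. For the chromatin columns the analysis notes give the unit expected count, because a format check read the fraction's abbreviation as chromosome, though the deposited values there are whole numbers like the rest. The Length column equals the gene span for all 37332 genes, so the deposited counts cover introns. Strand setting, multi-mapping and overlap rules are not stated per the labels, so counts of overlapping or antisense genes, and of near-identical families such as histone genes, are uncertain. The authors also deposited TPM for 53379 genes, which were used as an alternative measure. No coordinates were converted, and gene names and biotypes came from GENCODE vM21 by gene ID, which matched 35533 of the 37332 genes.

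All 27 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group, trimmed-mean scaling, the package's default low-count filter, which kept 18249 genes, and the quasi-likelihood test with 18 residual degrees of freedom. Comparisons were contrasts of the 9 group means, and the ratio comparisons were differences of chromatin-to-cytoplasm contrasts between cell types. Benjamini-Hochberg adjustment was at 0.05 within each comparison. Gene lists, fixed before the data were examined together with the design, the alternatives and the rule for naming genes, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 200 list tests, and again with estimated correlation. Genes named in the text were the 5 largest changes in each direction (2 for nucleoplasm versus cytoplasm) at a mean of 10 CPM or more, and genes fixed in advance, and 1 gene that met this rule is not reported here. CPM used the effective library sizes. Folds against a group at 0 counts used a floor of 3 counts per library and cover counting error only.

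Alternatives were DESeq2 1.42.0, median-ratio size factors, total-count scaling, trimmed-mean scaling without mitochondrial and structured RNA genes, no low-count filter, only the compared groups, a log2 fold change of at least 1, limma on log2(TPM + 1), the replicate number as a block, and leaving out each library in turn. Single genes were not tried with the second trimmed-mean scaling, no filter, only the compared groups or the fold change limit. Added after seeing the data were TPM rescaled by the median ratio and a fit without the libraries numbered 1 of mESC. Figures were drawn with matplotlib 3.10.9.

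The tests were tested on simulated data. In each simulation the compared groups shared a common mean except at the changed genes, which rose and fell in equal numbers. Libraries were drawn independently. Errors of scaling where most genes change, or of ignored pairing, were therefore not measured. For chromatin versus cytoplasm in mESC (17906 genes, 50 changed at each fold), edgeR recovered 25 at 1.5-fold, 44 at 2-fold and 50 at 4-fold and 8-fold. It called 12 of 17706 unchanged genes, or 6.6% of its calls. For the ratio in mNPC versus mESC (17594 genes) it recovered 3, 36, 49 and 50, and called 6 of 17394 unchanged genes, or 4.2% of its calls. In the first of these, limma made 84 false calls, or 32.4% of its calls, and 57 (25%) after rescaling. In the second it made 18 (11.6%), and 9 (6.2%) after rescaling. Here limma ran on scaled simulated counts and not on TPM, so the false calls of limma on TPM were not measured. DESeq2 made 22 false calls in the first (11.2% of its calls) and 20 in the second (11.9%).

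Replicate numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their group means. In mESC these ran from 0.37 to 0.74 over the fraction comparisons, and between chromatin and cytoplasm of mNPC from 0.13 to 0.29, so these samples were taken as paired from the data, and the replicate block gave 14943 genes for chromatin versus cytoplasm in mESC. Other mNPC fraction comparisons reached down to -0.05. Across cell types they ran from -0.13 to 0.12, and the numbers were not taken to pair cell types. In mCtx they ran from -0.13 to 0.19 and were not used to take its fractions as paired. Yet Xist rose from replicate 1 to 3 in each mCtx fraction. It was at 312, 970 and 2840 CPM in chromatin, 22.5, 108 and 188 in nucleoplasm and 7, 13 and 31.6 in cytoplasm. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty fell from replicate 1 to 3 in each mCtx fraction. Kdm5d went from 77 to 13.5 CPM in chromatin, from 48.6 to 6.93 in nucleoplasm and from 21.1 to 2.82 in cytoplasm. Same-numbered mCtx fractions therefore appear to come from the same culture. The main fit used no pairing in any cell type.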

Results

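Total RNA longer than 200 nt was sequenced after ribosomal RNA depletion from 3 subcellular fractions of 3 mouse cell types, to follow RNA from chromatin to cytoplasm along neuronal differentiation. The cell types were embryonic stem cells of the E14 line (mESC), a neural progenitor line (mNPC) and primary cortical neurons kept 5 days in culture (mCtx). Each was separated into chromatin-associated RNA, soluble nucleoplasm and cytoplasm, with 3 biological replicates per group, which made 27 libraries in 9 groups. Total counts per library ran from 11249862 to 19871198. Counts cover whole gene spans, introns included, so unspliced and spliced RNA of a gene are added together. Mature transfer RNAs, vault RNAs and microRNAs are shorter than 200 nt, so counts of their genes may come from other RNA, which was not tested. Levels are in CPM, counts scaled by effective library size, as mean ± SD over 3 libraries, log2 fold changes carry their standard error (SE), and adjusted p-values come from edgeR's quasi-likelihood test over 18249 genes with Benjamini-Hochberg adjustment at 0.05. Fold changes are relative to the trimmed-mean scaling of each library, so they compare shares of RNA within fractions and not amounts per cell.

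Long genes took a larger share of chromatin libraries in neurons than in the other cell types. Genes spanning 100 kb or more took 29.0% ± 2.08 of chromatin counts in mESC, 37.4% ± 1.09 in mNPC and 66.1% ± 1.25 in mCtx (SD, n = 3). In cytoplasm they took 8.34% ± 0.21, 9.45% ± 0.89 and 17.6% ± 0.68. Mitochondrial ribosomal RNA took 27.2% ± 1.05 of nucleoplasm counts in mESC, 5.33% ± 2.88 in mNPC and 0.66% ± 0.078 in mCtx.

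The comparison of chromatin with cytoplasm asks which transcripts take a larger share of one fraction than of the other. Leakage of nuclear RNA into the cytoplasm libraries was not tested, so a lower share on chromatin does not show export. In mESC, Immp2l, which encodes a mitochondrial inner membrane peptidase subunit and spans chromosome 12 from 41024090 to 41955588 (mm10), stood at 1399 ± 167 CPM in chromatin and 22.9 ± 1.28 in cytoplasm. The potassium channel gene Kcnd2, the glypican gene Gpc6, the heparanase-like gene Hpse2 and the ephrin gene Efna5 had log2 fold changes of 6.69, 6.67, 5.90 and 5.88, though Kcnd2 did not pass with TPM (0.20) or rescaled TPM (0.17). Lower in chromatin were the histone genes Hist1h4f (-5.15) and Hist1h4h (-5.06), the enolase gene Eno1b (-5.34), the microRNA gene Mir686 (-5.78, and 0 with TPM, where it did not pass) and the vault RNA gene Vaultrc5 (-5.02). Gabbr1, which encodes a subunit of the GABA-B receptor (chromosome 17, 37045966 to 37075067), was higher in chromatin by a log2 fold change of 2.12 (SE 0.16, edgeR adjusted p = 7.32e-12). Ptbp1, which encodes a splicing repressor (chromosome 10, 79854427 to 79864771), was lower in chromatin by -2.92 (SE 0.18), while its neural paralog Ptbp2 (chromosome 3, 119718742 to 119783388) was higher by 1.88 (SE 0.15). Malat1, a nuclear long noncoding RNA, was higher by 2.12, and beta-actin (Actb) was lower by -4.62. Of 18249 genes, 14138 passed, 8130 higher and 6008 lower in chromatin. Scaling by total counts alone made that split 9813 and 4635.

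All 88 tested ribosomal protein genes were lower in mESC chromatin, as were 88 when adjusted over the list alone (median log2 fold change -3.42, camera adjusted p = 3.5e-60). Of 74 nuclear genes for oxidative phosphorylation, 69 were lower and 3 higher, and 70 were lower adjusted over the list alone (median -2.38, camera adjusted p = 3.24e-31). Of 62 replication-dependent histone genes, 57 were lower and 3 higher (median -4.04, camera adjusted p = 6.88e-17, 0.208 with the correlation between genes estimated). Of 14 nuclear long noncoding RNAs, 11 were higher and none lower (median 2.95, or 2.84 with genes at 0 set to their bound, camera adjusted p = 2.64e-06). Synaptic receptor and channel genes were higher in 30 of 34 and lower in 2 (median 2.55, 0.51 with TPM and 0.47 with rescaled TPM, camera adjusted p = 1.72e-05, 0.102 with estimated correlation). By counts, all protein-coding genes of 100 kb or more had a median of 2.24 in mESC, and lists were not compared with genes of like span. Neural RNA-binding protein genes were higher in 18 of 28 and lower in 5 (median 1.56, 0.53 with TPM and 0.72 with rescaled TPM, camera adjusted p = 0.000407, 0.119 with estimated correlation). Mitochondrially encoded genes were higher in 7 of 10 (camera adjusted p = 0.0448, 0.0883 with total counts, 0.0551 without the mESC chromatin library numbered 1 and 0.505 with estimated correlation). The lists of snoRNA host genes, structured noncoding RNAs, secretory-pathway chaperones, immediate early genes and detained-intron genes (genes with introns kept in polyadenylated nuclear RNA) did not pass camera in this comparison, though immediate early genes (camera adjusted p = 0.244) passed with the replicate block (camera adjusted p = 0.0252) and without the low-count filter (camera adjusted p = 0.0313).

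In mNPC, the netrin receptor gene Dcc (chromosome 18, 71258738 to 72351069) stood at 1873 ± 209 CPM in chromatin and 17.6 ± 2.04 in cytoplasm. Csmd1, which encodes a large membrane protein, and the neurexin gene Nrxn3 had log2 fold changes of 6.77 and 6.62, beside the small nucleolar RNA gene Snord17 (6.98) and Phxr4 (6.92). Lower in chromatin were Vaultrc5 (-6.14), the histone genes Hist1h4b (-6.02), Hist1h4f (-6.02) and Hist2h4 (-5.98), and the ribosomal protein gene Rpl28 (-5.93). Gabbr1 did not differ between the fractions by counts, at 117 ± 12.6 and 123 ± 12.6 CPM (edgeR adjusted p = 0.732), whereas transcript-level TPM put it higher in chromatin by 1.11. Ptbp1 was lower by -1.69 (SE 0.17) by counts and did not pass with TPM (-0.41) or rescaled TPM (-0.01). Ptbp2 was higher by 2.39 (SE 0.15), Malat1 higher by 3.96 and Actb lower by -4. In all, 12686 genes passed, 6753 higher and 5933 lower. Ribosomal protein genes were lower in 85 of 88 (median -4.91) and oxidative phosphorylation genes in 70 of 74 (median -3.30), with the same counts adjusted over each list alone. Histone genes were lower in 57 of 62 (median -4.63, or -4.61 with genes at 0 at their bound, camera adjusted p = 2.88e-20, 0.165 with estimated correlation). Detained-intron genes were higher in 27 of 33 and lower in 3 (median 1.28, camera adjusted p = 1.03e-07, 0.107 with estimated correlation). Nuclear long noncoding RNAs were higher in 12 of 14 and lower in 1 (camera adjusted p = 0.00034, 0.0624 with estimated correlation). Synaptic genes were higher in 26 of 34 and lower in 1 (median 2.20, or 2.56 with genes at 0 at their bound, 0.29 with TPM and 0.47 with rescaled TPM, camera adjusted p = 3.56e-08). Neural RNA-binding protein genes were higher in 16 of 28 (median 1.04, 0.17 with TPM and 0.51 with rescaled TPM, camera adjusted p = 0.000723, 0.107 with estimated correlation). Secretory-pathway chaperones were lower in 17 of 26 (median -0.91, camera adjusted p = 0.00561, 0.276 with estimated correlation), a median that became 0.03 with rescaled TPM.

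In mCtx, Kcnip4, which encodes a potassium channel-interacting protein (chromosome 5, 48389502 to 49524904), stood at 4944 ± 621 CPM in chromatin and 61.4 ± 6.75 in cytoplasm. Xist, the X-inactivation RNA, had a log2 fold change of 6.33 with 1373 ± 1310 CPM in chromatin, and the Tsix gene covers 100% of its span on the opposite strand. The retrotransposon-derived gene Rtl4 (6.10), the exchange-factor gene Rasgef1b (6.08) and the sarcoglycan gene Sgcz (5.97) were also higher. Lower were Tmsb4x, encoding thymosin beta 4 (-6.61), the histone genes Hist1h2bk (-6.79) and Hist1h4k (-6.74), Vaultrc5 (-7.01) and the cytokine receptor gene Il31ra (-7.56), whose cytoplasmic level of 362 ± 483 CPM varied widely and whose direction turned with TPM. Gabbr1 was lower in chromatin by counts, -2.09 (SE 0.16, edgeR adjusted p = 4.21e-12), at 106 ± 4.33 against 450.1 ± 11 CPM, but did not pass with TPM (0.48) or rescaled TPM (-0.05). Ptbp1 was lower by -1.13 by counts and higher by 1.43 with TPM. Ptbp2 was higher by 0.97 (SE 0.15), Dlg4, which encodes the postsynaptic scaffold PSD-95 (chromosome 11, 70017085 to 70045532), was lower by -2.09 (SE 0.22) by counts and did not pass with TPM (-0.40), and Actb was lower by -4.83. Malat1 did not pass by counts, at 0.44 (SE 0.26, edgeR adjusted p = 0.137), and was -0.13 with total counts. It passed with 5 alternatives, the replicate block among them (0.44, edgeR adjusted p = 0.00634). In all, 13370 genes passed, 6500 higher and 6870 lower, a split of 4841 and 8646 with total counts and of 7374 and 6016 with median-ratio size factors. Ribosomal protein genes were lower in 85 of 88 (median -5.07) and oxidative phosphorylation genes in 69 of 74 (median -3.52), or 70 adjusted over the list alone. Histone genes were lower in 53 of 62 (median -5.25, or -5.14 with genes at 0 at their bound, camera adjusted p = 5.16e-15, 0.253 with estimated correlation). Synaptic genes were higher in 28 of 34 (median 2.52, 1.89 with TPM and 1.38 with rescaled TPM, camera adjusted p = 9.17e-08), neural RNA-binding protein genes in 22 of 28 (camera adjusted p = 1.44e-05, 0.0582 with estimated correlation) and nuclear long noncoding RNAs in 11 of 14 (camera adjusted p = 0.00698, 0.156 with estimated correlation). Secretory-pathway chaperones were lower in 19 of 26 (camera adjusted p = 0.00364, 0.245 with estimated correlation) and structured noncoding RNAs in 4 of 5 (camera adjusted p = 0.0159, 0.276 with estimated correlation). Detained-intron genes were higher in 19 of 33 (camera adjusted p = 0.0412, 0.188 with total counts and 0.551 with estimated correlation).

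**Figure D1:**
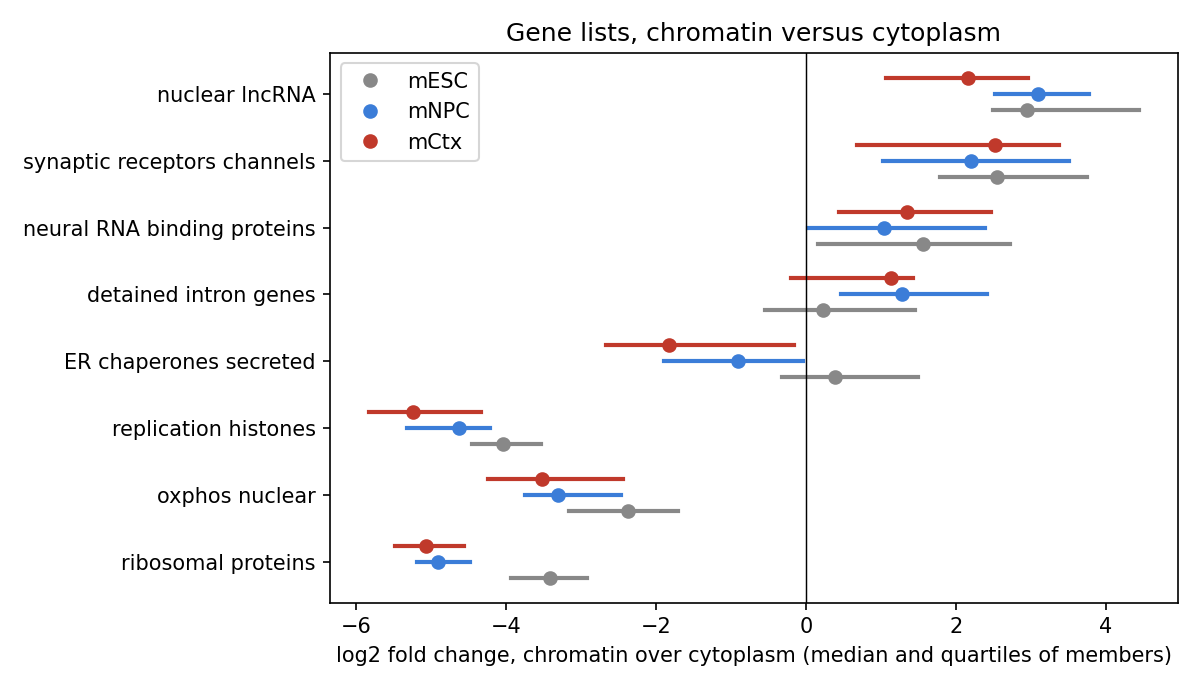
Median log2 fold change of chromatin over cytoplasm for the members of 8 gene lists in mESC, mNPC and mCtx, with lines from the lower to the upper quartile of members. Ribosomal protein, oxidative phosphorylation and histone lists lie below 0 in all 3 cell types, and the secretory chaperone list in mNPC, here at -0.91, is at 0.03 with rescaled TPM.

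The sorting of genes between chromatin and cytoplasm was largely shared by the 3 cell types. Of 11703 genes at 1 CPM or more in all 3, 3124 were higher and 3577 lower in chromatin in every cell type. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.847 between mESC and mNPC, 0.784 between mESC and mCtx and 0.896 between mNPC and mCtx. Protein-coding genes with several exons had higher chromatin fold changes the longer their span, with a Spearman rho across genes of 0.633 in mESC, 0.627 in mNPC and 0.766 in mCtx. With rescaled TPM the rho was 0.323, 0.352 and 0.463. Over all protein-coding genes, those with a single exon included, the median in mCtx was -2.29 for 2859 genes under 10 kb and 2.27 for 2127 genes of 100 kb or more.

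**Figure D2:**
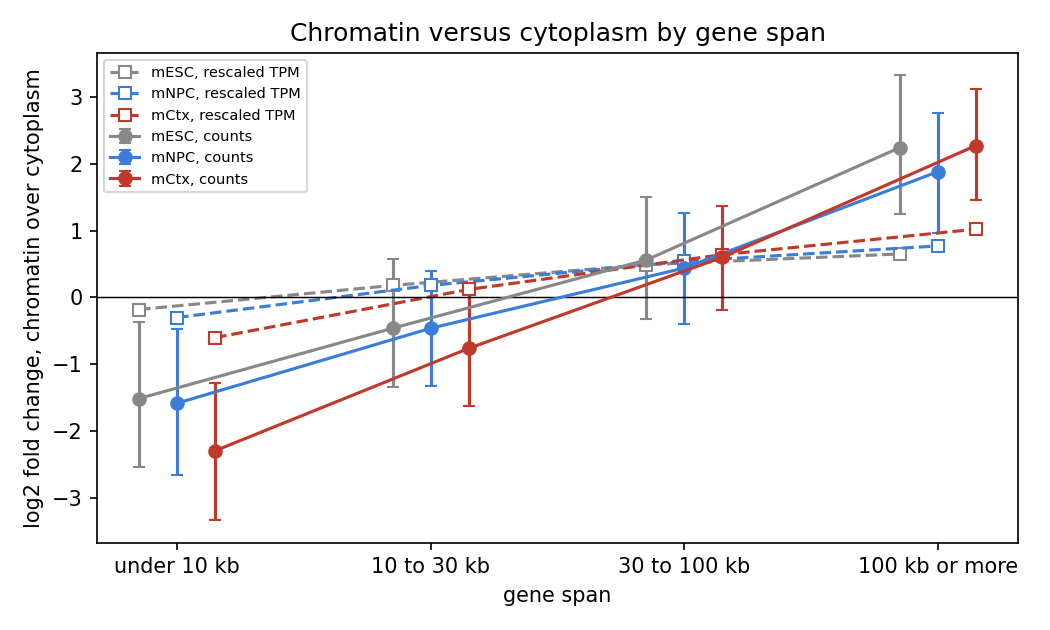
Median log2 fold change of chromatin over cytoplasm by gene span for protein-coding genes in mESC, mNPC and mCtx, from counts (filled circles, bars from lower to upper quartile) and from rescaled TPM (open squares). In mCtx the count medians run from -2.29 under 10 kb to 2.27 at 100 kb or more, and the TPM medians from -0.60 to 1.02.

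The next comparison is of nucleoplasm with chromatin. In mESC, mt-Cytb, which encodes cytochrome b, stood at 1503 ± 79.7 CPM in nucleoplasm and 52.0 ± 14.1 in chromatin, and the complex I genes mt-Nd6, mt-Nd4, mt-Nd2 and mt-Nd5 had log2 fold changes of 5.40, 4.97, 4.68 and 4.48. Immp2l (-4.09), the DNA repair gene Rad51b (-4.05), Hpse2 (-4.05), Snord17 (-4.01) and the antisense transcript Lrrc75aos2 (-5.28) were lower in nucleoplasm. Gabbr1 was lower by -1.44 (SE 0.16, edgeR adjusted p = 1.34e-08). In all, 12092 genes passed, 5467 higher and 6625 lower, and 3241 and 9691 with total counts. Mitochondrially encoded genes were higher in 10 of 10 (median 4.58, or 4.46 with genes at 0 at their bound), ribosomal protein genes in 87 of 88, or 88 adjusted over the list alone, and secretory-pathway chaperones in 25 of 26. Neural RNA-binding protein genes were lower in 20 of 28 (camera adjusted p = 1.22e-05, 0.0582 with estimated correlation), and synaptic genes in 28 of 34 (camera adjusted p = 1.84e-05, 0.0818 with estimated correlation).

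In mNPC, the mitochondrial ribosomal RNA mt-Rnr2 stood at 56900 ± 34910 CPM in nucleoplasm and 388 ± 74.8 in chromatin. The ribosomal RNA mt-Rnr1 (7.78), mt-Cytb (6.06), mt-Nd4 (6.03) and the transfer RNA gene mt-Tl1 (6.02) were also higher in nucleoplasm. The long genes Fhit, encoding a diadenosine hydrolase (-5.69), Sgcz (-5.12) and Fbxl7 (-5.03) were lower, with Phxr4 at -4.99, and Sgcz did not pass with TPM (-0.06) or rescaled TPM (-0.09). Gabbr1 was higher in nucleoplasm by 1.47 by counts (SE 0.16, edgeR adjusted p = 4.14e-09) and did not pass with TPM (-0.25) or rescaled TPM (0.09). In all, 12053 genes passed, 5937 higher and 6116 lower, and 4461 and 7796 with total counts. Detained-intron genes were lower in nucleoplasm in 30 of 33 and higher in 1 (median -1.26, camera adjusted p = 2.45e-09, 0.0703 with estimated correlation). Mitochondrially encoded genes were higher in 10 of 10 and secretory-pathway chaperones in 26 of 26.

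In mCtx, mt-Rnr2 (4.70), mt-Rnr1 (4.66), mt-Nd6 (4.65), the transfer RNA gene mt-Tw (4.38) and Banf1, which encodes a chromatin-binding factor (4.61), were higher in nucleoplasm than in chromatin. Xist (-3.69), the transcription factor genes Glis1 (-2.51) and Tcf7l1 (-2.34), the kinase gene Ulk4 (-2.24) and the ligand gene Wnt5b (-2.29 by counts, 0.40 with TPM) were lower. Gabbr1 was higher by 1.72 (SE 0.16, edgeR adjusted p = 6.62e-10) and did not pass with TPM (0.27). In all, 10424 genes passed, 5579 higher and 4845 lower, and the larger side turned with the scaling, at 6737 and 3444 with total counts but 4715 and 6063 with median-ratio size factors. Mitochondrially encoded genes were higher in 9 of 10 (camera adjusted p = 1.67e-06, 0.0894 with estimated correlation) and ribosomal protein genes in 85 of 88.

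Between nucleoplasm and cytoplasm, secretory-pathway chaperones were higher in nucleoplasm in 25 of 26 in mESC (median 3.08, camera adjusted p = 3.51e-27) and 21 of 26 in mNPC (median 2.37, camera adjusted p = 4.03e-19). In mCtx 12 were higher and 7 lower (median 0.22, -0.11 with total counts, 1.46 with TPM and 0.77 with rescaled TPM, camera adjusted p = 0.296). Mitochondrially encoded genes had medians of 7.25 in mESC, 6.005 in mNPC and 1.725 in mCtx (camera adjusted p = 0.419 with estimated correlation in mCtx). Mitochondrial mRNA took 1.85% of nucleoplasm and 0.014% of cytoplasm counts in mESC, 5.72% and 0.12% in mNPC, and 1.45% and 0.65% in mCtx. The nucleoplasm libraries thus held RNA from outside the nucleus, and a higher share there does not place an RNA inside the nucleus. How much other RNA from outside the nucleus they held was not tested. Among single genes in mESC, mt-Nd6 stood at 210.5 ± 76.1 CPM in nucleoplasm and 0.62 ± 0.24 in cytoplasm, and mt-Tw at 26.3 ± 2.84 and 0.056 ± 0.054. Vaultrc5 (-3.67) and the RNase P-like gene Rprl3 (-3.16) were lower, and Gabbr1 was higher by 0.68, which did not pass with TPM (0.65). In mNPC, mt-Rnr1 (7.67) and mt-Rnr2 (7.28) were higher, Vaultrc5 (-3.86) and the histone gene Hist1h4j (-3.36) lower, and Gabbr1 higher by 1.40. In mCtx, Kcnip4 (5.05) and Sgcz (4.81) were higher, Vaultrc5 (-5.21) and Il31ra (-7.10, 0.33 with TPM) lower, and Gabbr1 at -0.38 by counts and 0.75 with TPM. The Gabbr1 value did not pass with DESeq2 or median-ratio size factors (-0.30 with each), nor without any 1 of 5 of the 6 libraries. The genes past edgeR's threshold were 11518 in mESC (5452 higher, 6066 lower), 9139 in mNPC (4119 and 5020) and 10625 in mCtx (5405 and 5220). Total counts made the last 2 splits 3296 and 6472, and 4060 and 6933.

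Neural progenitors held less of the pluripotency messages of stem cells and more neural progenitor messages. In cytoplasm, Pou5f1, which encodes the pluripotency factor OCT4 (chromosome 17, 35506037 to 35510776), stood at 805 ± 170 CPM in mESC and was at 0 counts in mNPC, at least 4510-fold lower against a floor of 3 counts per library. Dppa5a and Zfp42, other stem cell genes, the threonine dehydrogenase gene Tdh and the RNA-binding gene L1td1 were also at 0 in mNPC, from 895 ± 45, 876 ± 62.2, 666 ± 73.1 and 486 ± 182 CPM. Fabp7, a fatty acid-binding protein gene of radial glia, stood at 1740 ± 327 CPM in mNPC and 0.058 ± 0.061 in mESC. The endothelin receptor gene Ednrb (1033 ± 198), the astrocyte gene Mlc1 (449.8 ± 58.6), the glutamate carrier gene Slc25a18 (199 ± 21.8) and the noncoding RNA Pantr1 (131 ± 1.82) were under 0.1 CPM in mESC. Gabbr1 was higher by 2.98 (SE 0.17), Ptbp2 by 1.24 (SE 0.15, not past the threshold with TPM at 0.38) and Dlg4 by 1.92 (SE 0.23), Ptbp1 was lower by -2.06 (SE 0.17), and the imprinted RNA Meg3 went from 24.4 ± 10.4 to 0.036 ± 0.062 CPM. In all, 13864 genes passed with edgeR, 6668 higher and 7196 lower in mNPC. Pluripotency genes were lower in 25 of 25 (camera adjusted p = 1.02e-28), neural progenitor genes higher in 20 of 24 (camera adjusted p = 7.48e-19), astrocyte genes in 12 of 13 (camera adjusted p = 8.4e-10) and oligodendrocyte lineage genes in 10 of 11 (camera adjusted p = 1.14e-07). Endoderm and trophoblast genes were lower in 8 of 8 (camera adjusted p = 0.00659, 0.172 with estimated correlation), and cell cycle genes in 19 of 28, or 21 adjusted over the list alone (camera adjusted p = 0.0012, 0.494 with estimated correlation). Synaptic genes were higher in 21 of 34 (camera adjusted p = 0.00206, 0.245 with estimated correlation). The lists for neural RNA-binding protein, pan-neuronal, projection neuron, interneuron, microglial, endothelial and meningeal genes did not pass.

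On chromatin, the glutamate receptor gene Gria2 stood at 498 ± 29.6 CPM in mNPC chromatin and 0.034 ± 0.029 in mESC, the adhesion gene Lsamp at 2012 ± 124 and 0.53 ± 0.36, and Ednrb at 644 ± 84.9 and 0.13 ± 0.14. The oligodendrocyte lineage factor gene Olig2 stood at 186 ± 24.8 and the microRNA gene Mir3093 at 42.4 ± 7.90 CPM in mNPC. Zfp42 (348 ± 58.3 CPM in mESC), the zinc finger gene Zfp990 (188 ± 25.8), the amino acid transporter gene Slc38a4 (161 ± 21.1), L1td1 (138 ± 12.6) and Triml1 (124 ± 22.2) were at 0 counts in mNPC. Gabbr1 was higher by 0.79 by counts (SE 0.15) and did not pass with TPM (-0.51) or rescaled TPM (0.36). Ptbp1 was lower by -0.82, and Ptbp2 (1.75) and Dlg4 (1.37, not past the threshold with TPM at 0.50) were higher. Meg3 went from 172 ± 67.6 to 0.48 ± 0.30 CPM. In all, 13959 genes passed with edgeR, 6173 higher and 7786 lower. Pluripotency genes were lower in 25 of 25 and neural progenitor genes higher in 21 of 24. Synaptic genes were higher in 20 of 34 and lower in 12 (median 0.99, -0.02 with TPM, camera adjusted p = 8.07e-05, 0.135 with estimated correlation), and interneuron genes in 6 of 15 with 4 lower (median 1.38, or 1.68 with genes at 0 at their bound, -0.05 with TPM, camera adjusted p = 0.0254, 0.0949 without the low-count filter and 0.061 with estimated correlation).

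Cortical neurons held more neuronal messages than progenitors. In cytoplasm, Stmn2, which encodes a microtubule regulator of growing axons (chromosome 3, 8509527 to 8561604), stood at 1026 ± 51.1 CPM in mCtx and 0.042 ± 0.037 in mNPC. Mpped1 (607 ± 30), the neuregulin gene Nrg3 (199 ± 21.0), the adaptor gene Sla (178 ± 7.86) and the synaptic adhesion gene Lrfn5 (157 ± 5.12) were at 0 counts in mNPC. The angiotensinogen gene Agt, the cardiac actin gene Actc1 (104 ± 17.2 CPM in mNPC), the connexin gene Gjc3 (54.4 ± 4.91), the glial gene S100b (38.9 ± 7.79) and the histone gene Hist1h4m (68.0 ± 15.7) were under 0.2 CPM in mCtx. Gabbr1 was higher by 1.88 (SE 0.16), Ptbp2 by 1.23 and Dlg4 by 1.81, Ptbp1 was lower by -1.32, and Meg3 stood at 299 ± 39.6 CPM. In all, 12043 genes passed with edgeR, 5951 higher and 6092 lower. Synaptic genes were higher in 34 of 34 (camera adjusted p = 1.48e-28), pan-neuronal genes in 27 of 28 (camera adjusted p = 1.04e-26), projection neuron genes in 16 of 18 (camera adjusted p = 1.27e-15), interneuron genes in 15 of 15 (camera adjusted p = 4.86e-07) and neural RNA-binding protein genes in 19 of 28 (camera adjusted p = 5.26e-09). Cell cycle genes were lower in 27 of 28 (camera adjusted p = 3.45e-16, 0.0702 with estimated correlation), neural progenitor genes in 20 of 24 (camera adjusted p = 1.67e-06), oligodendrocyte lineage genes in 9 of 11 (camera adjusted p = 1.22e-07) and astrocyte genes in 11 of 13 (camera adjusted p = 0.00178, 0.172 with estimated correlation). Microglial genes were higher in 11 of 12 (median 7.01, or 3.49 with genes at 0 at their bound, camera adjusted p = 0.00306, 0.0785 with estimated correlation).

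On chromatin, Nrg3 (chromosome 14, 38368952 to 39473088) stood at 10260 ± 1360 CPM in mCtx and 0.091 ± 0.16 in mNPC. Lrfn5 (2190 ± 293 CPM), Mpped1 (539 ± 8.27), Stmn2 (339 ± 3.08) and Tcerg1l (300.8 ± 8) were under 0.1 CPM in mNPC. The oligodendrocyte genes Aspa (34.8 ± 2.63 CPM in mNPC) and Gpr17 (23.2 ± 4.37) and Actc1 (28.3 ± 4.25) were at 0 counts in mCtx, while the plexin gene Plxnb3 (149 ± 35.9) and Agt (28.3 ± 5.62) were under 0.2 CPM. Gabbr1 did not pass by counts (-0.15, SE 0.15, edgeR adjusted p = 0.4) and passed at -0.75 with total counts and 1.38 with TPM. Ptbp2 did not pass either (-0.19) and passed at -0.80 with total counts and 1.30 with TPM, Ptbp1 was lower by -0.76 (0.90 with TPM), and Dlg4 was higher by 0.85, which did not pass with total counts (0.24). Meg3 stood at 1522 ± 20.5 CPM in mCtx. In all, 12657 genes passed with edgeR, 5505 higher and 7152 lower, and the larger side turned with the scaling, at 3751 and 9835 with total counts but 6513 and 5835 with median-ratio size factors. Synaptic genes were higher in 33 of 34, pan-neuronal genes in 25 of 28 and projection neuron genes in 16 of 18. Cell cycle genes were lower in 27 of 28 (camera adjusted p = 1.64e-13, 0.104 with estimated correlation) and neural progenitor genes in 22 of 24 (camera adjusted p = 8.32e-09). Interneuron genes were higher in 9 of 15 (camera adjusted p = 0.0321, 0.0785 with estimated correlation), and microglial genes in 7 of 12 did not pass as a list (camera adjusted p = 0.602).

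The ratio comparisons ask whether the balance of a gene's RNA between chromatin and cytoplasm differs between cell types. Gabbr1 had a lower ratio in mNPC than in mESC, and in mCtx than in mNPC. The cell types are separate lines and a primary culture, so source cannot be told apart from stage of differentiation. The Gabbr1 ratio was lower by -2.19 (SE 0.22) in mNPC than in mESC, by -2.02 (SE 0.22) in mCtx than in mNPC and by -4.22 (SE 0.23) in mCtx than in mESC (edgeR adjusted p = 1.85e-08, 8.77e-08 and 2e-13). It was below 0 with every alternative run for single genes, though it did not pass from mNPC to mCtx with TPM (-0.63). Ptbp1 went the other way, higher by 1.23 (SE 0.23) in mNPC than in mESC and by 1.79 (SE 0.24) in mCtx than in mESC. Malat1 was higher by 1.84 (SE 0.37) in mNPC than in mESC and lower by -3.52 (SE 0.38) in mCtx than in mNPC. Malat1 took 0.67% of cytoplasm counts in mCtx, beside 0.61% of its chromatin counts. In cytoplasm of mNPC and mESC it took 0.14% and 0.13%. Purity of the fractions was not compared between cell types, so ratio differences cannot be told apart from differing purity.

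**Figure D3:**
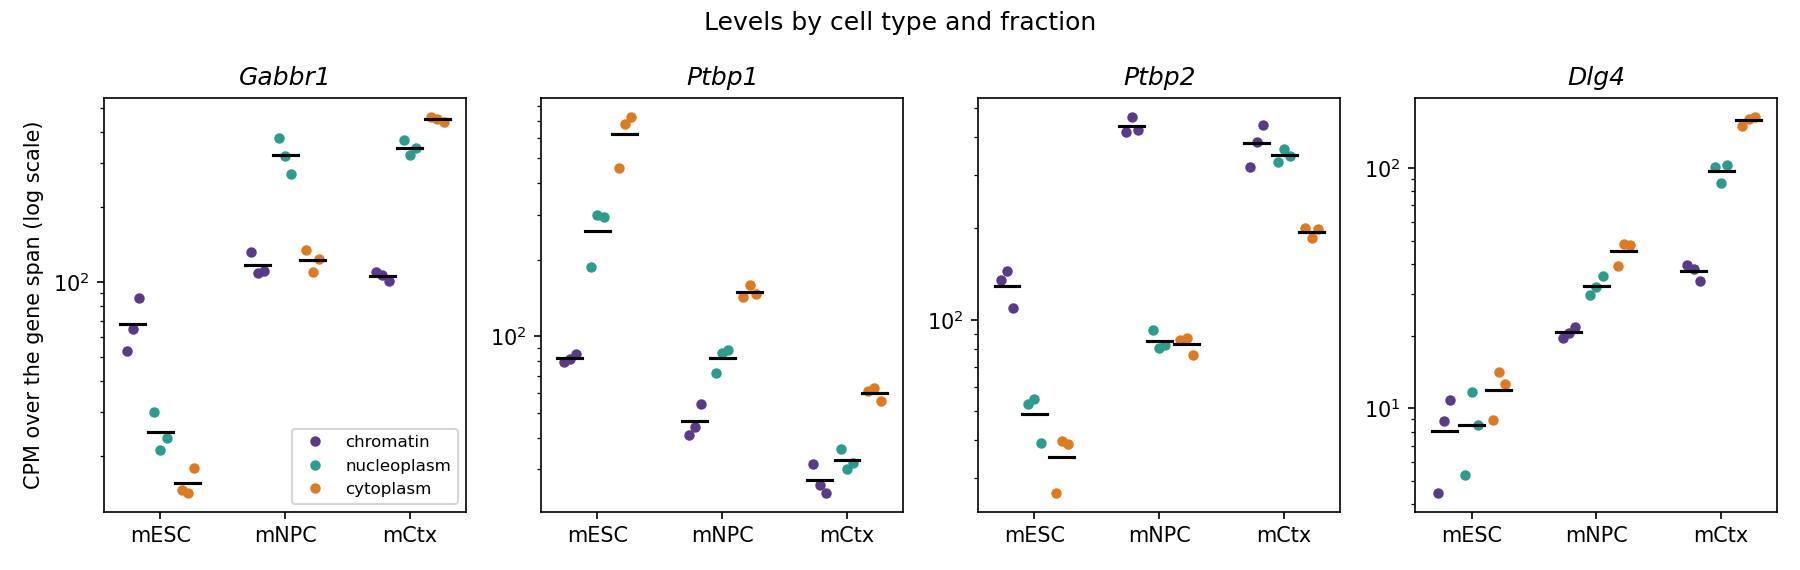
CPM over the gene span (log axis) of Gabbr1, Ptbp1, Ptbp2 and Dlg4 in chromatin, nucleoplasm and cytoplasm of mESC, mNPC and mCtx, with 1 point per library and a bar at the mean of 3. Gabbr1 in cytoplasm goes from 15.6 CPM in mESC to 450.1 in mCtx, against 67.9 and 106 on chromatin.

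Between mESC and mNPC, genes with detained introns had higher chromatin-to-cytoplasm ratios and secretory genes lower ones. Detained-intron genes had a higher ratio in mNPC in 28 of 33 and a lower one in none, or 1 adjusted over the list alone (median 0.92, camera adjusted p = 5.54e-15, 0.0223 with estimated correlation). Secretory-pathway chaperones had a lower ratio in 24 of 26 (median -1.40, camera adjusted p = 3.91e-11), ribosomal protein genes in 79 of 88 (median -1.37, camera adjusted p = 2.65e-29, 0.0977 with estimated correlation) and oxidative phosphorylation genes in 44 of 74 (camera adjusted p = 6.7e-07, 0.271 with estimated correlation). Of single genes, the receptor genes Lrp1b (6.87) and Il1rapl1 (6.47) and the inositol synthase gene Isyna1 (5.42) rose, and Olfm2 fell by 4.50 on the log2 scale. Ifitm1, Lin28a, Slc25a18, Plxdc1, Zfp978 and Smagp, also among the 10 genes furthest apart, were under 1 CPM in both fractions of mNPC, or at 0 counts in mESC cytoplasm for Slc25a18, so no ratio is given. Ptbp2 (0.51) and Dlg4 (-0.55) did not pass without a block (edgeR adjusted p = 0.0512 and 0.181). With the replicate block, which fits the pairing of these samples, both passed (Ptbp2 0.52, edgeR adjusted p = 0.0244, and Dlg4 -0.52, edgeR adjusted p = 0.0138). Ptbp2 also passed with DESeq2, median-ratio size factors and rescaled TPM (0.66), and Dlg4 with total counts (-0.84). Without the 3 mESC libraries numbered 1 both passed (Ptbp2 0.69 and Dlg4 -0.7). In all, 7337 genes passed, 3047 higher and 4290 lower, and 1942 and 5663 with total counts.

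Between mNPC and mCtx, detained-intron genes had lower ratios in 24 of 33 and higher ones in 2, or 25 and 2 adjusted over the list alone (median -0.87, 0.35 with TPM and -0.6 with rescaled TPM, camera adjusted p = 2.4e-09, 0.0749 with estimated correlation). Immediate early genes were lower in 11 of 25 and higher in none, or 14 lower adjusted over the list alone (camera adjusted p = 0.000891, 0.0758 with total counts and 0.375 with estimated correlation). Mllt11 (chromosome 3, 95219135 to 95228677) had a ratio lower by -4.67 (SE 0.30), from 30.01 ± 1.57 and 11.1 ± 1.16 CPM on chromatin and in cytoplasm of mNPC to 41.8 ± 1.42 and 390.2 ± 20.9 in mCtx. The receptor gene Gpr21 (-5.74, 0.31 with TPM) and mt-Rnr1 (-5.18) were lower, and the transporter gene Slc35f4 (4.57) and Cntnap5b (4.05) higher, both from under 1 CPM in mNPC. Slc35f4 did not pass with rescaled TPM (0.12), nor Cntnap5b without 1 of the mNPC cytoplasm libraries. Efcab6, Celf6, Lin28b, Nefl, which encodes neurofilament light chain, and Rtn4rl2 were under 1 CPM in both mNPC fractions. Ptbp2 was lower by -1.42 (SE 0.21) by counts and was 0.07 with TPM. Dlg4 was lower by -0.96 (SE 0.30) and did not pass with median-ratio size factors or DESeq2 (-0.73 with each) or TPM (-0.28). Ptbp1 did not pass (0.56, edgeR adjusted p = 0.0718), was -0.18 with total counts, and passed with the replicate block (0.56), median-ratio size factors and DESeq2 (0.80 with each), TPM (1.84) and rescaled TPM (0.94). In all, 6204 genes passed, 2227 higher and 3977 lower. That split rests on the scaling, being 3189 and 2775 with median-ratio size factors and 538 and 9186 with total counts.

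From mESC to mCtx, Lrp1b (6.62), Il1rapl1 (5.31) and the potassium channel gene Kcnk2 (5.08, not past the threshold with rescaled TPM at 0.21) had higher ratios, and the mitochondrial ribosomal RNAs mt-Rnr1 (-8.51) and mt-Rnr2 (-6.97) lower ones. Mir692-2, Tgm1 and Zfp978 were under 1 CPM in both mCtx fractions, and the somatostatin gene Sst and the cortical factor gene Tbr1 were at 0 counts in mESC cytoplasm. Ptbp2 (-0.91, 0.58 with TPM) and Dlg4 (-1.52) were lower, and Malat1 was lower by -1.68, while Dlg4 (-0.64) and Malat1 (-0.38) did not pass with TPM. Mitochondrially encoded genes were lower in 7 of 10 (camera adjusted p = 1.22e-07, 0.0702 with estimated correlation), ribosomal protein genes in 79 of 88 (camera adjusted p = 3.38e-21, 0.164 with estimated correlation), secretory-pathway chaperones in 22 of 26, or 26 adjusted over the list alone (camera adjusted p = 2.25e-09), and histone genes in 36 of 62 (camera adjusted p = 0.0153, 0.349 with total counts and 0.75 with estimated correlation). Oxidative phosphorylation genes were lower in 48 of 74 (median -1.03, 0.07 with TPM and -0.83 with rescaled TPM, camera adjusted p = 3.98e-05, 0.37 with estimated correlation). In all, 9157 genes passed with edgeR, 3221 higher and 5936 lower, and 4254 and 4743 with median-ratio size factors.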

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

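The tests in this part were chosen after seeing the results, except that the predictions on single-exon genes, exonic length and nuclear-encoded ribosomal RNA were written before those values were computed. Related correlations, such as the span trend with TPM, had been seen before the span predictions.

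The chromatin-to-cytoplasm fold change rose with gene span. If reads from introns alone gave this, single-exon genes should have shown a much weaker trend, under 0.5 times that of genes with several exons, but their Spearman rho was 0.556 in mESC, 0.619 in mNPC and 0.579 in mCtx, against 0.633, 0.627 and 0.766 for genes with several exons. Counting against that hypothesis would have needed over 0.9 times in all 3 cell types, bootstrap bounds included, which was not met either, so the test cannot tell. Single-exon genes include replication histone genes, which were not separated. Their span is also their exonic length, so their rho and that of genes with several exons measure trends with different lengths. For genes with several exons, length of the exonic sequence alone does not account for the trend, since the partial rho given exonic length was 0.453 or more.

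Mitochondrial ribosomal RNA took 27.2% of nucleoplasm counts in mESC. More mitochondrial RNA of every kind would predict more mitochondrial mRNA as well, which was 1.85% in mESC nucleoplasm, below the 5.72% in mNPC, against that hypothesis for mESC and mNPC. In mCtx nucleoplasm it was 1.45%, a small difference beside that in ribosomal RNA (0.66% in mCtx). Less complete removal of ribosomal RNA cannot be told apart, since nuclear-encoded ribosomal RNA in mESC was at 0.000157% in nucleoplasm and 0.000125% in cytoplasm, between 0.000185% and 0.000137% in mCtx and 8.64e-05% and 7.14e-05% in mNPC, while on chromatin it was at 0.000475%, below 0.000556% in mNPC and 0.000609% in mCtx but with overlapping libraries. These shares are of 339 genes annotated as ribosomal RNA. Whether those genes stand for the abundant ribosomal RNAs was not checked, so their shares may not report on removal. The ratio of mitochondrial ribosomal RNA to mRNA ran from 14 to 35.4 in mESC libraries from 0.283 to 1.21 in mNPC and from 0.21 to 1.25 in mCtx, so more of every kind alike does not account for the difference from either, and what does stays open.

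Xist differed 9.09-fold among the mCtx chromatin libraries. One hypothesis is that the cultures held different shares of XX and XY cells, and 4 Y-linked genes in the culture with the highest Xist were at 0.19 of the mean of the others, as that would predict. Chromatin fractions of different purity would move other nuclear long noncoding RNAs as well, and the largest ratio among 12 of them was 1.26.

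Group labels could be rearranged into only 10 splits per comparison, so the real grouping's share, 1 of 10, could never be under 0.1 and cannot tell. The highest count in any other split was 25, 1 and 0 for chromatin versus cytoplasm in mESC, mNPC and mCtx, 1505, 0 and 0 for nucleoplasm versus chromatin, 2519, 0 and 3 for nucleoplasm versus cytoplasm, 1 and 0 for the 2 cytoplasm comparisons of cell types, and 0 for the others. The 1505 and 2519 in mESC came from splits that parted only 1 same-numbered pair. Other splits that parted all 3 pairs called 0 genes in each mESC fraction comparison.

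Chromatin-to-cytoplasm ratios differed between mNPC and mESC for 7337 genes. Lrp1b was at 6.87, Il1rapl1 at 6.47, Isyna1 at 5.42, Malat1 at 1.84, Ptbp1 at 1.23, Gabbr1 at -2.19 and Olfm2 at -4.50 on the log2 scale. List medians were 0.92 for detained-intron genes, -0.20 for snoRNA host genes, -0.74 for oxidative phosphorylation, -0.80 for histones, -1.37 for ribosomal proteins, -1.40 for secretory chaperones and -2.55 for mitochondrially encoded genes. With estimated correlation the camera adjusted p was 0.405 for snoRNA host genes, which also did not pass with the replicate block (0.0863), 0.234 for mitochondrially encoded genes and 0.742 for histones.

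Between mCtx and mNPC 6204 genes differed. Slc35f4 was at 4.57, Cntnap5b at 4.05, Dlg4 at -0.96, Ptbp2 at -1.42, Gabbr1 at -2.02, Malat1 at -3.52, Mllt11 at -4.67, Nefl at -5.14, mt-Rnr1 at -5.18 and Gpr21 at -5.74. Slc35f4, Cntnap5b and Nefl were under 1 CPM in mNPC, so their values rest on few counts there. List medians were -0.87 for detained-intron genes (0.35 with TPM and -0.6 with rescaled TPM), -1.61 for immediate early genes and -2.04 for mitochondrially encoded genes (camera adjusted p = 0.208 with estimated correlation).

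Between mCtx and mESC 9157 genes differed. Lrp1b was at 6.62, Il1rapl1 at 5.31, Kcnk2 at 5.08, Ptbp1 at 1.79, Ptbp2 at -0.91, Dlg4 at -1.52, Malat1 at -1.68, Gabbr1 at -4.22, mt-Rnr2 at -6.97 and mt-Rnr1 at -8.51. List medians were -1.03 for oxidative phosphorylation (0.07 with TPM and -0.83 with rescaled TPM), -1.32 for histones, -1.57 for snoRNA host genes, -1.60 for ribosomal proteins, -1.70 for secretory chaperones, -2.46 for structured noncoding RNAs and -4.34 for mitochondrially encoded genes. With estimated correlation the camera adjusted p was 0.245 for snoRNA host genes and 0.285 for structured noncoding RNAs, which also did not pass with total counts (0.0578).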

How the results depend on the processing

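Of 199 gene values checked, 155 kept their call under every alternative run for single genes and 17 turned direction with a call on at least 1 side, all with TPM or TPM rescaled by the median ratio (the latter added after seeing the data), and the cause was not tested. Values that passed neither way also turned without TPM, as Malat1 in chromatin versus cytoplasm of mCtx did with total counts (-0.13). With TPM and rescaled TPM, chromatin versus cytoplasm was 1.11 and 1.54 for Gabbr1 in mNPC, and in mCtx 0.48 and -0.05 for Gabbr1, 1.43 and 0.93 for Ptbp1 and 0.75 and 0.61 for Il31ra. Nucleoplasm versus chromatin was -0.25 and 0.09 for Gabbr1 in mNPC, and 0.40 and 0.28 for Wnt5b in mCtx. Nucleoplasm versus cytoplasm in mCtx was 0.33 and 0.20 for Il31ra and 0.75 and 0.06 for Gabbr1, which also missed the threshold with DESeq2 and median-ratio size factors (-0.30 with each) and without any 1 of 5 of the 6 libraries (edgeR adjusted p from 0.0567 to 0.103). On chromatin, Gabbr1 was -0.51 and 0.36 in mNPC versus mESC, and mCtx versus mNPC was 1.38 and 0.51 for Gabbr1, 0.90 and 0.06 for Ptbp1 and 1.30 and 0.42 for Ptbp2. Ratios were 2.06 and 1.75 for Smagp (mNPC versus mESC), which was under 1 CPM in both mNPC fractions, 0.31 for Gpr21 and 0.07 for Ptbp2 with TPM (mCtx versus mNPC), and 0.71 and 0.36 for Tbr1, at 0 counts in mESC cytoplasm, and 0.58 for Ptbp2 with TPM (mCtx versus mESC). No ratio is given for Smagp and Tbr1 in the results for that reason.

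Counts of genes moved over 1.5-fold with limma on TPM for mCtx versus mNPC in cytoplasm (7873, not 12043) and for the ratio in mCtx versus mNPC (9399, of which 8788 higher and 611 lower, and 9724 with total counts, not 6204). Requiring a log2 fold change of 1 left 7865 and 6005 for nucleoplasm versus chromatin in mESC and mCtx, 7001, 4504 and 6179 for nucleoplasm versus cytoplasm in mESC, mNPC and mCtx, and 4517 and 3520 for the ratios in mNPC versus mESC and mCtx versus mNPC. With the correlation between genes estimated, 55 list tests passed, not 120. The replicate block gave 14943 genes for chromatin versus cytoplasm in mESC, not 14138, and 128 list tests. For fraction and ratio comparisons the block was the replicate number within each cell type. For comparisons of cell types it was shared across cell types, though the numbers were not taken to pair these. The 128 include both kinds. With total counts the ratio in mCtx versus mESC split into 730 higher and 10988 lower, and the median of all genes moved by -1.03, the largest shift. With TPM the split for chromatin versus cytoplasm in mCtx was 10197 higher and 2646 lower (8944 and 4193 with rescaled TPM), and on chromatin in mCtx versus mNPC 11056 and 1422. Whether more genes were higher or lower turned with at least 1 alternative in all comparisons except chromatin versus cytoplasm in mESC and mNPC, mNPC versus mESC on chromatin and their ratio. Leaving out 1 library kept every count within 1.5-fold, as from 5454 to 5896 for the ratio in mCtx versus mNPC. The cause of these differences was not tested.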

Other observations

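The values in this part were looked up after seeing the results. Among the mCtx libraries, chromatin Xist was at 312, 970 and 2840 CPM in replicates 1, 2 and 3, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty differed 5.76-fold, 5.78-fold, 5.72-fold and 5.62-fold. Meg3 was at 0.48 ± 0.30 CPM on chromatin in mNPC (n = 3), below the 172 ± 67.6 in mESC and the 1522 ± 20.5 in mCtx. Ednrb, the endothelin receptor gene, was at 4877 ± 1343 CPM in nucleoplasm of mNPC and 1033 ± 198 in cytoplasm.

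The mESC culture numbered 1 stood apart, with 350 of 15370 genes over 2-fold higher and 68 lower in all 3 fractions than the other mESC cultures. The culture numbered 3 had 33 and 192, the one numbered 2 had 20 and 8, and no mNPC or mCtx culture passed 13 in either direction.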
